A study of Mus musculus with 2 samples.

How the data were processed

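H3K27ac, the acetylation of lysine 27 of histone H3 that marks active promoters and enhancers, was measured by ChIP-seq in kidneys of mouse embryos at embryonic day 15.5, per the labels. The strain was B6NCrl and male and female embryos were mixed. The 2 samples form a single group and are biological replicates, of 78 embryos (replicate 1) and 62 embryos (replicate 2). No second tissue, stage or treatment was part of the design, so the only comparison between samples was between the replicates. All other comparisons were between genes or regions within the same tissue.

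Peak lists on the mouse build mm10 were analysed, not reads. Per the deposited descriptions, the authors called peaks in each replicate on its own and on both replicates together. They also derived a list of replicated peaks. It was not a plain overlap of the replicates' own lists, since 797 of its peaks were touched by neither. The peak caller, its version, the aligner and the rule for a replicated peak were not given in the sources used here. The fold of a peak is the authors' own fold enrichment over its background, and it was used to describe, rank and filter peaks. Fold was also compared between genes or chromosomes of the same list by medians, and between the replicates by correlations and ratios. The −log10 p-value and −log10 q-value of each peak were also deposited by the authors. The lowest deposited −log10 p-value in each list was about 2, and no threshold on q was visible in the values. No read counts were analysed here, so the depth of each sample is unknown, and intervals cover counting error over peaks or genes only.

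Peaks on the 19 autosomes, X and Y were used. Genes, transcripts and exons came from GENCODE M21 and the sequence from GRCm38, the same build as mm10. A peak was shared between replicates when at least 50% of either peak was covered. Overlaps were compared with 100 shuffles of peak positions within chromosomes, with assembly gaps left out. A protein-coding gene was called marked when a peak overlapped 1000 bp on either side of any of its annotated transcription start sites (TSSs). A distal peak overlapped no such window of any gene class, and distal peaks were counted within 50 kb of the TSSs of a gene. Annotated start sites can lie inside a gene, as at the promoter peaks given below for Egf, Egfl7 and Pdzk1.

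The 25 gene lists, the main tests, the rule for named genes and the alternatives other than those named as later were fixed before the data were examined. Of the listed symbols, 1 (Ahsp) had no match. Marked members were compared with all other protein-coding genes by the two-sided Fisher exact test. The median fold of marked members and the mean number of distal peaks were compared with 10000 random lists of the same size, in two-sided permutation tests whose smallest p is 2.0e-04. Fold was tested only for the 17 lists with at least 3 marked members. All p-values were adjusted by the Benjamini-Hochberg method over the lists, with a threshold of 0.05. Genes are not independent replicates, and neighbouring genes can share a peak. In addition, random lists were matched on the ratio of observed to expected CpG within 500 bp of the TSS.

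Peaks were stitched over gaps of up to 12500 bp into domains, which were ranked by the sum of fold times length. Large domains lay above the point where the scaled ranked curve has a slope of 1. Each was assigned the protein-coding genes with a TSS inside it or, failing that, the gene with the nearest TSS. Consensus sites were searched on both strands in 1000 bp windows around summits of distal peaks. Each window had a control window 5 to 50 kb away, outside all peaks and TSS windows, within 2 percentage points of its GC content, chosen from 40 drawn positions. Ratios of windows with a site carry 95% intervals from 1000 bootstrap draws over chromosomes. After the counts were seen, ratios were withheld for sites with fewer than 10 control windows, which removed REST and POU5F1-SOX2 in the replicated list. Neither had an interval in that list that left out 1. Site ratios by distance from the summit, ratios in the narrower peaks, the CpG-matched test of fold and the tests of explanations for the X chromosome were added after the first results were seen. Peaks per Mb on X and Y were set against the autosomes.

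The rule for named genes took the 3 marked members of each list with the highest fold and up to 4 unmarked members in alphabetical order. It also took the 3 members with most distal peaks in lists past the threshold, the 10 highest-ranked domains and the 5 replicated peaks with the highest fold. The 5 strongest peaks of each replicate that touched no peak of the other replicate completed it. Other genes in the text, apart from those that share a peak with a named gene, were chosen after their values were seen.

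Alternatives covered the promoter window, the overlap rule, a threshold of 0.01 on q, the distal window, the stitching distance, the motif window and controls, matched backgrounds, and each replicate's list in place of the replicated list. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Overlap, Pearson correlation, the promoter and distal list tests, domains and motif ratios were tested on simulated data. The fold test, the matched tests, list members in domains and the X measures were not. In the simulation of list promoter tests, a list marked at 95% against 56% was called in 85.0% of 40 runs, and 0.208% of unchanged lists were called. The simulated shared peaks made up 59.8% of 20000 peaks, and 59.8% were found. Peaks on unplaced scaffolds were left out of all tests because gene positions were taken from chromosomes.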

Results

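The data comprised 4 peak lists of H3K27ac in the mouse kidney at embryonic day 15.5, a stage at which nephron progenitors, a branching ureteric tree, stroma and vessels are present together. Replicate 1 (78 embryos) had 111025 peaks with a median width of 332 bp. Replicate 2 (62 embryos) had 108793 peaks with a median width of 334 bp. The authors' list from both replicates together held 141194 peaks, and their replicated list held 72792 peaks, which covered 2.73% of the genome. Depth was unknown, since no read counts were analysed here. Fold values below are the authors' fold enrichment per peak in the replicated list, with values of replicates 1 and 2 in brackets where given.

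Genes of the kidney's progenitor field carried acetylated promoters more often than other genes. Of the 20 nephron progenitor genes, 19 were marked, against 56.5% of other protein-coding genes (Fisher exact test, adjusted p = 0.00108), a call that ended with matching on promoter CpG (0.137). Sall1, a zinc-finger factor needed for the ureteric bud to enter the mesenchyme, had the strongest peak of the list at 29.8-fold (23.2 in replicate 1 and 20.5 in replicate 2). Fgf20, a growth factor that maintains progenitors, reached 25.2-fold, at a peak that also covered the TSS window of Micu3. Pax2, required for the kidney to form, reached 23.9-fold. Six1 was the unmarked member. Early nephron genes were marked in 16 of 20 cases (exact adjusted p = 0.0541), led by the Notch ligand Jag1 at 27.5-fold, Emx2 at 21.04-fold and cyclin D1 (Ccnd1) at 19.5-fold (12.1 and 21.3). Bmp2, Fgf8, Irx1 and Pcsk9 were unmarked.

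The ureteric bud and collecting duct list was marked in 19 of 24 cases (exact adjusted p = 0.0538). Its strongest promoters were Hoxb7 at 35.4-fold, Spry1, an inhibitor of RET signalling, at 22.3-fold, and Emx2. The value of Hoxb7 came from a peak of 71749 bp shared with other Hoxb genes, with its summit 687 bp from the TSS of Hoxb4. Aqp2, the vasopressin-regulated water channel, Calb1, Foxi1 and Upk1b were unmarked. Signalling genes were marked more often than other genes, with 18 of 20 genes of GDNF and RET signalling and 18 of 20 WNT targets and modulators (exact adjusted p = 0.00460 for each). Matched on promoter CpG, neither call held (permutation adjusted p = 0.904 and 0.752). Spry2 reached 33.6-fold (20.7 and 30.9) and Dusp6, a phosphatase that damps ERK signalling, reached 28.1-fold, while Crlf1 and Grem1 were unmarked. Axin2, a feedback target of WNT signalling, had 41.4-fold (30.1 and 42.6 in the replicates), Lgr4 had 33.5-fold and Fzd7 had 28.2-fold (17.6 and 29.4), while Porcn and Rspo3 were unmarked. These were the highest of the WNT list, whose 18 marked genes had a median of 6.97, against 10.6 for random lists of marked genes. That difference did not pass the threshold (permutation adjusted p = 0.114, and 0.0589 with CpG matching). The median of the GDNF and RET list was 11.1.

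Stroma and endothelium were also marked more often than other genes. Among 20 stromal genes, 18 were marked (exact adjusted p = 0.00460), with the homeobox factors Pbx1 at 33.8-fold, Meis1 at 27.4-fold and Meis2 at 25.7-fold. Ren1, which encodes renin, and Smoc2 were unmarked. Among 18 endothelial genes, 16 were marked (exact adjusted p = 0.0116), led by Emcn at 10.8-fold, Esam at 8.31-fold and Egfl7 at 8.05-fold, with Gja4 and Tie1 unmarked. All 18 housekeeping genes were marked (exact adjusted p = 2.10e-04; 0.134 with CpG matching), including Ywhaz at 51.2-fold, Actb at 41.3-fold and Hmbs at 35.7-fold.

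Lists of differentiated nephron segments did not pass the threshold for how often they were marked. Podocyte genes were marked in 15 of 20 cases (exact adjusted p = 0.126), led by the forkhead factors Foxc1 at 33.1-fold and Foxc2 at 25.1-fold and by Vegfa at 22.4-fold. The slit diaphragm genes Nphs1 (nephrin) and Nphs2 (podocin) had no promoter peak in either replicate. Lmx1b and Plce1 were marked in replicate 1 only. Proximal tubule genes were marked in 11 of 20 cases and loop of Henle and distal tubule genes in 10 of 18 (exact adjusted p = 1.00 for each). Apart from the transcription factor Hnf1a at 16.5-fold, the strongest proximal tubule promoters were Pdzk1 at 4.29-fold and the organic anion transporter Slc22a6 at 3.96-fold, and Ass1, Fbp1, Gatm and Hnf4g were unmarked. In the loop and distal tubule list, Sim1 reached 14.6-fold, Cldn19 11.9-fold and Egf 10.4-fold, while Cldn16, Esrrb, Ppp1r1b and Pvalb were unmarked. The Egf peak (chromosome 3, 129724536 to 129725424) lay at an internal annotated start site, far from both ends of the gene (129677565 to 129755316).

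The height of marked promoters also differed from random lists in 6 of the 17 lists tested, but in none against lists matched on promoter CpG, a test added after the first results were seen. Marked proximal tubule genes had a median fold of 3.76 (3.98 and 3.83 in the replicates), against 10.7 for random lists of marked genes (permutation test, adjusted p = 0.00340; 0.0748 with matching). Loop of Henle and distal tubule genes had a median of 4.09 and endothelial genes one of 4.63 (permutation adjusted p = 0.00567 for each; 0.0748 with matching). The 5 marked liver genes had 3.38 (permutation adjusted p = 0.0136; 0.0589 with matching), and the 6 marked receptor genes of the olfactory and vomeronasal list had 4.42 (permutation adjusted p = 0.0428; 0.412 with matching). Housekeeping promoters had a higher median of 17.6 (permutation adjusted p = 0.0453; 0.0748 with matching). Nephron progenitor promoters, at 12.5, did not differ from random lists (permutation adjusted p = 0.671), nor did stromal promoters at 10.8 (permutation adjusted p = 0.944).

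Genes of other organs were marked less often. None of 24 transcription factors of other organs was marked in the replicated list or in either replicate (exact adjusted p = 2.55e-08), among them Atoh1, Barhl1, Barhl2 and the intestinal factor Cdx2. Neuronal genes were marked in 1 of 18 cases (Elavl4 at 7.16-fold, exact adjusted p = 6.21e-05), with Ascl1, Chat, Dbh and Elavl3 unmarked. Pluripotency and germ cell genes were marked in 1 of 16 cases (Dazl at 3.51-fold, exact adjusted p = 2.10e-04), and skeletal and cardiac muscle genes in 1 of 15 (Tnnt3 at 5.61-fold, exact adjusted p = 3.18e-04; 0.0906 with CpG matching). Genes of the adrenal and gonad, which adjoin the kidney, were marked in 2 of 16 cases (exact adjusted p = 0.00131; 0.0775 with CpG matching). The 2 were Inha at 20.7-fold, whose peak also covered an Obsl1 start site, and Mc2r at 2.86-fold. Keratins of hair and skin were marked in 2 of 14 cases (exact adjusted p = 0.00456; 0.184 with CpG matching), Krt10 at 35.2-fold and Ivl at 2.56-fold, the latter with no promoter peak in replicate 1. Of 1465 olfactory and vomeronasal receptor genes, 6 were marked (0.410%, p below 1.0e-300), with Vmn1r4 at 16.4-fold, at a peak that also covered the TSS window of Nt5c3, and Olfr1033 next at 5.33-fold. Reads shared between close copies of these receptor genes were not analysed here.

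Markers of blood and of other cell types that a dissected kidney can hold gave mixed counts. Macrophage and leukocyte genes were marked in 2 of 18 cases (exact adjusted p = 4.32e-04; 0.453 with CpG matching), Aif1 at 4.68-fold and Cd68 at 4.55-fold, while the complement genes C1qa, C1qb and C1qc were unmarked. Each replicate's own list marked 4 of the 18 macrophage and leukocyte genes, 3 of them in both. Erythroid genes were marked in 4 of 15 cases (exact adjusted p = 0.0522). Tal1, a blood and endothelial factor, had 6.10-fold, and Klf1 had 9.14-fold, with no promoter peak in replicate 1 and 3.15-fold in replicate 2. The replicated Klf1 peak (chromosome 8, 84902928 to 84903611) lay inside the gene, which starts at 84901928, at the edge of the 1000 bp window. Peaks of a replicate just outside that window were not counted, so the Klf1 values do not show a difference between replicates. Alas2, Epb42, Gata1 and Gfi1b were unmarked. Schwann and glial genes were marked in 3 of 12 cases (exact adjusted p = 0.0538), namely Erbb3, Mbp and Mpz, whose peak also covered an Sdhc start site. Liver genes were marked in 5 of 16 cases (exact adjusted p = 0.0579), led by Hhex at 9.74-fold, with Ahsg, Alb, Apoa1 and Apoa2 unmarked, though Apoa2 had peaks of 2.83-fold and 3.32-fold in the replicates' own lists.

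**Figure D1:**
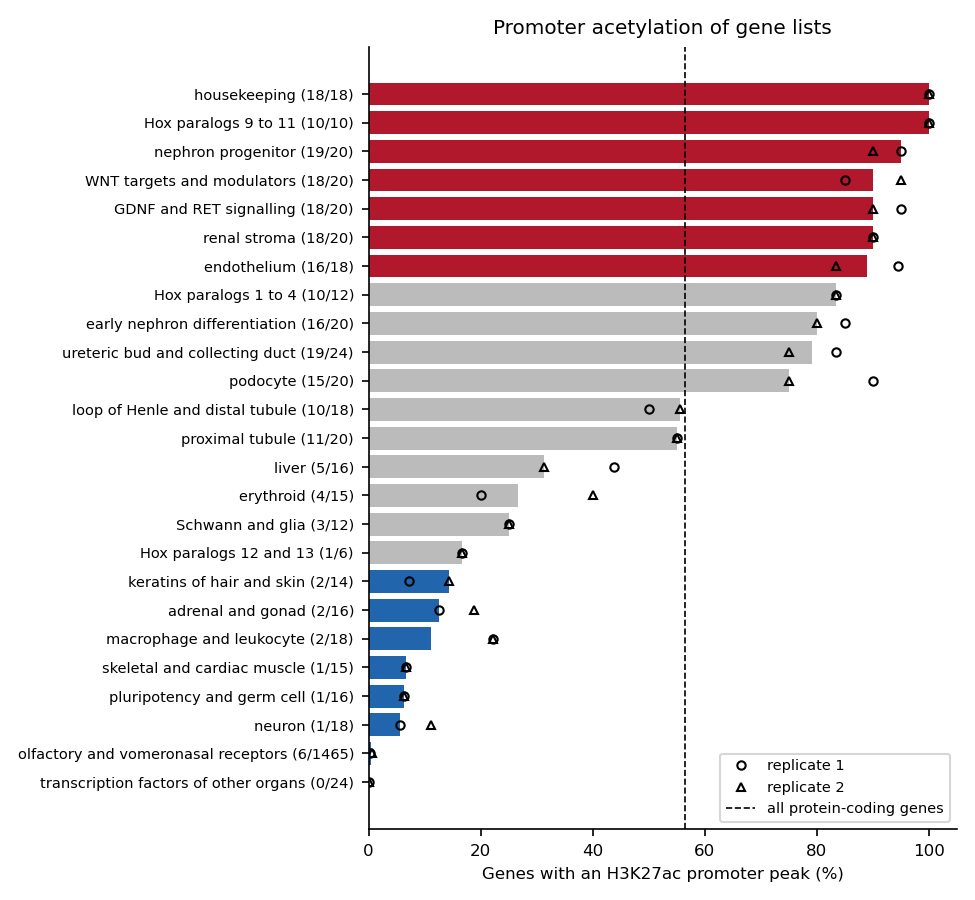
Share of genes with an H3K27ac promoter peak (percent, horizontal axis) in each gene list, with marked and total members in brackets. Bars give the replicated list (red, more often and blue, less often than other genes at an adjusted p of 0.05 or less; grey, not past it), circles and triangles give replicates 1 and 2, and the dashed line is the 56.5% of all protein-coding genes.

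CpG content of promoters moved with these calls. Of genes above the median of the promoter CpG ratio, 86.4% were marked, against 26.7% of those below it. Against random lists matched on that ratio, stroma (permutation adjusted p = 9.999e-04) and endothelium (permutation adjusted p = 0.00417) were still marked more often in permutation tests. Neuronal genes, transcription factors of other organs, pluripotency genes and receptor genes were still marked less often (permutation adjusted p = 9.999e-04 for each). Nephron progenitor, housekeeping, signalling, macrophage, muscle, adrenal and gonad, and keratin genes no longer passed the threshold. Since most CpG-rich promoters were marked, the matched test had little room to call a CpG-rich list as marked more often. All 18 housekeeping genes were marked, the highest count possible, and that list still did not pass. The endothelial call also ended with the list of replicate 2 alone (Fisher exact test, adjusted p = 0.0511) and with only the first TSS of each gene (0.0813).

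Of the Hox genes, only paralog groups 9 to 11 passed the threshold, and the groups were not tested against each other. All 10 genes of these groups, which pattern the kidney's mesenchyme, were marked (exact adjusted p = 0.0116), at 28.9-fold for Hoxa9 (20.2 and 16.2), 23.3-fold for Hoxb9 and 22.2-fold for Hoxa10. Of the 6 genes of groups 12 and 13, 1 was marked, Hoxd12 at 6.35-fold (exact adjusted p = 0.105), and Hoxa13, Hoxb13, Hoxc12 and Hoxc13 were unmarked. Groups 1 to 4 were marked in 10 of 12 cases (exact adjusted p = 0.0955), with Hoxb1 and Hoxd1 unmarked. Against random lists matched on promoter CpG, the low count of groups 12 and 13 passed the threshold (permutation adjusted p = 0.0150), and the count of groups 9 to 11 did not (permutation adjusted p = 0.360). With all 10 genes marked no higher count was possible, so the matched test had no room to call groups 9 to 11. The peak of Hoxa9 was 17135 bp wide and shared with Hoxa3 and Hoxa7. Hox genes share clusters and are not independent: Hoxb3 to Hoxb8 had their strongest promoter peak in common, a peak of 71749 bp at chromosome 11, 96275784 to 96347532, with 35.4-fold, the widest of the replicated list.

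Over all protein-coding genes, 12352 of 21851 were marked in the replicated list, 12625 in replicate 1 and 12568 in replicate 2. Both replicates marked 12142 genes, and 483 genes had a promoter peak in replicate 1 only and 426 in replicate 2 only. Examples from the fixed lists were Bmp2 at 2.37-fold and Calb1 at 2.74-fold in replicate 1 only, and Fbp1 at 2.81-fold in replicate 2 only. Across genes marked in both, the fold ranks correlated with a Spearman rho of 0.909 and the log2 folds with a Pearson r of 0.905. These correlations are across genes, which are not independent replicates.

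Peaks outside promoters surrounded genes of several kidney lineages. Ureteric bud and collecting duct genes had a mean of 7.88 distal peaks within 50 kb, against 3.10 for random lists (permutation test, adjusted p = 0.00167, at the smallest raw p of 2.0e-04). The cadherin gene Cdh1 and the transcription factor gene Hnf1b had 16 each, and Gfra1, a co-receptor of RET, had 15. WNT targets and modulators had a mean of 7.50 (permutation adjusted p = 0.00167), with 22 at Nkd1, 21 at Tcf7l2 and 14 at Znrf3. Endothelial genes had 7.06 (permutation adjusted p = 0.00833), with 19 at Eng, 18 at Egfl7 and 13 at Kdr, a VEGF receptor. Podocyte genes had 6.25 (permutation adjusted p = 0.0117), with 19 at Synpo, 16 at Tjp1 and 13 at Podxl. Nephron progenitor genes had 5.85 (permutation adjusted p = 0.0300), with 16 each at Sall1 and Wt1 and 15 at Pax2. Early nephron genes had 5.65 (permutation adjusted p = 0.0408), with 23 at Pax8, 15 at Jag1 and 12 at Pou3f3. This last call ended without replicate 1 (permutation adjusted p = 0.0586) and with a window of 100 kb (0.154), and the endothelial call ended with each peak given to its nearest TSS (0.0550).

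Hox genes of groups 1 to 4 had a mean of 9.08 distal peaks (permutation adjusted p = 0.00375), with 30 at Hoxc4, 10 at Hoxb1 and 8 at Hoxa3. Groups 9 to 11 had 8.50 (permutation adjusted p = 0.0117), with 18 at Hoxc9 and 14 each at Hoxc10 and Hoxc11. Neighbours in a cluster share these peaks, and with each peak given to its nearest TSS only, neither call held (permutation adjusted p = 0.578 and 0.545). Fewer distal peaks lay near receptor genes (0.124, permutation adjusted p = 0.00167), transcription factors of other organs (0.917, permutation adjusted p = 0.00700), keratins (0.643, permutation adjusted p = 0.0117) and pluripotency genes (1.00, permutation adjusted p = 0.0300). The call for other organs ended with assignment to the nearest TSS (0.161), and that for pluripotency genes with it and with windows of 20 or 100 kb (0.0641 to 0.0985). In these lists, Foxn1 had 9 distal peaks, Olfr750 had 7, Stra8 had 4 and Krtdap had 3. The remaining 13 lists did not pass the threshold, including stroma (5.20, permutation adjusted p = 0.0843), GDNF and RET signalling (5.5, permutation adjusted p = 0.0562), proximal tubule (4.60, permutation adjusted p = 0.207) and housekeeping (4.44, permutation adjusted p = 0.287). Means of the others were 3.67 in loop of Henle and distal tubule, 3.47 in erythroid, 3.33 in Hox 12 and 13, 2.80 in muscle, 2.75 in Schwann and glia, 2.56 in adrenal and gonad, 2.50 in macrophage, 1.94 in liver and 1.5 in neuron genes.

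**Figure D2:**
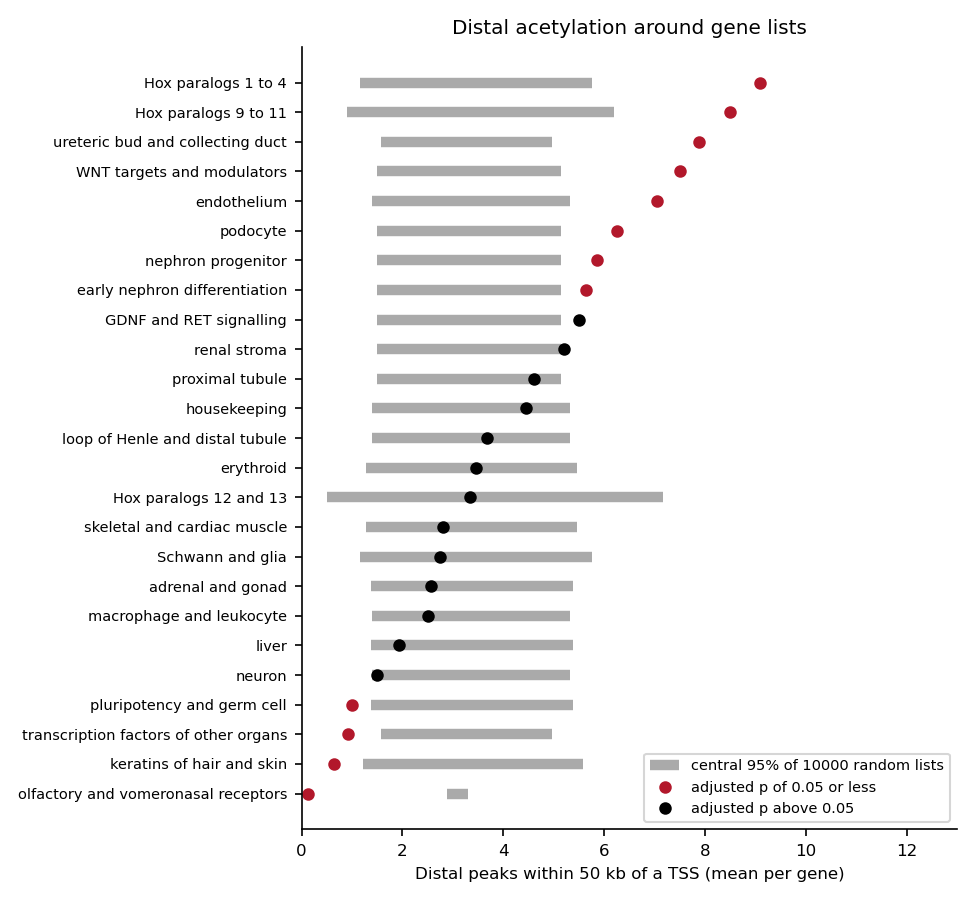
Mean number of distal H3K27ac peaks within 50 kb of the TSSs of each list's genes (horizontal axis, peaks per gene). Points are list means (red, adjusted p of 0.05 or less), and grey bars are the central 95% of 10000 random lists of the same size; Hox groups 1 to 4 lie highest at 9.08 and receptor genes lowest at 0.124.

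Stitching gave 24888 domains, of which 702 were large, with a median span of 53.1 kb, and these held 22.6% of the peak length. The highest-ranked domain covered Hoxb1 to Hoxb9 (chromosome 11, 96250223 to 96448595) and the domain ranked 3 covered Hoxa1 to Hoxa11 (chromosome 6, 52158221 to 52249918). Ranked by peak length they came 3 and 8, and with peaks within 2500 bp of a TSS left out no Hox cluster was among the first 10. Leaving out such peaks removes wide peaks that span TSSs, such as the one over Hoxb3 to Hoxb8, by construction. Rank 2 held Cstad and Ntmt1 (chromosome 2, 30586606 to 30809052), rank 4 Irf2bpl, rank 6 Cxxc5 and rank 7 Ctsd, Lsp1, Tnnt3, Tnni2, Syt8 and Mrpl23. Rank 5 (chromosome 12, 79704125 to 80023700) held no protein-coding TSS and lay nearest Zfp36l1. Ranks 8 to 10 held Trim8, Arl3 and Sfxn2, then Ahdc1 and Wasf2, then Bahcc1 and Slc38a10. The clusters of Hoxd and Hoxc, named after their ranks were seen, ranked 12 and 13.

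Large domains were assigned 1639 genes in all, by a TSS inside or, failing that, by the nearest TSS. They included 6 of 20 nephron progenitor genes, namely Pax2, Sall1, Wt1, Hoxa11, Hoxc11 and, named after its value was seen, Hoxd11 (Fisher exact test, adjusted p = 0.0137), and 9 of 18 housekeeping genes (exact adjusted p = 1.20e-05). All 10 Hox genes of groups 9 to 11 and 11 of 12 of groups 1 to 4 lay in large domains (exact adjusted p = 4.58e-11 for each), but each set came from 4 domains. Hoxa11, Hoxc11 and Hoxd11 belong to both the progenitor list and groups 9 to 11, so those calls are not independent. The progenitor list was not tested without these genes. None of the 1465 receptor genes lay in one (exact adjusted p = 1.41e-50), and the other 20 lists did not pass the threshold. With peaks within 2500 bp of a TSS left out, 489 large domains were assigned 464 genes, and most of the 10 highest-ranked held no TSS. None of the progenitor, housekeeping or Hox 9 to 11 genes and 1 of 12 Hox 1 to 4 genes (exact adjusted p = 0.946) was assigned to a large domain. Ureteric bud (exact adjusted p = 0.00107) and stromal genes (exact adjusted p = 6.29e-04) were assigned more often than other genes, often perhaps only as the nearest gene. This setting removes promoter peaks by construction, so it cannot test domains built on them. The progenitor call also ended with the list of either replicate alone (exact adjusted p = 0.0854 and 0.0931).

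Most of the consensus sites searched were more common around distal summits than in control windows matched on GC, and kidney factors were not tested against others. The 51221 windows with a control contained an HNF1 site in 0.301% of cases against 0.0449% of controls, a ratio of 6.70 (95% interval 4.70 to 12.5), with the higher share on 20 of 21 chromosomes. HNF1 factors (Hnf1a and Hnf1b) act in renal epithelia. Ratios were 2.84 (2.00 to 4.19) for NFI, 2.27 (1.95 to 2.64) for MEF2, 1.83 (1.44 to 2.34) for GRHL/TFCP2 and 1.81 (1.66 to 1.95) for ETS. The ETS family has members in the endothelial list (Erg) and in the ureteric bud list (Etv4 and Etv5). HOX-PBX sites had 1.61 (1.52 to 1.71), WT1/EGR sites 1.53 (1.40 to 1.66), Six2-type sites (TCAGGTTTC) 1.43 (1.31 to 1.57), CTCF sites 1.41 (1.27 to 1.57), TEAD sites 1.37 (1.32 to 1.40) and PAX2/8 sites 1.34 (1.07 to 1.74).

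Weaker ratios were found for HOX9-13 (1.30), FOX (1.29), E-box (1.20), TFAP2 (1.19), HNF4 (1.18), SOX (1.14), GATA (1.13), AP-1 (1.10) and RUNX (1.10) sites, all with intervals above 1. NRF1 sites had 1.66 (1.10 to 2.72). The intervals of LEF/TCF (1.03, 0.979 to 1.08) and RFX (1.14, 0.986 to 1.34) included 1. POU5F1-SOX2 sites, in 4 windows and 1 control, and REST sites, in 7 windows and 9 controls, were too rare for a ratio. In the list of replicate 2 alone REST sites had 0.261 (0.0769 to 0.534), and in that of replicate 1 alone 0.387 (0.228 to 0.634). NRF1 turned to 0.857 with controls matched on CpG as well. In windows of 200 bp CTCF turned to 0.303 and RFX to 0.527 (0.352 to 0.750). In windows of 200 bp, HNF1 sites were in 3 windows and 3 controls and NFI sites in 14 and 9, and the intervals of AP-1, HNF4, HOX-PBX, Six2-type, PAX2/8, GRHL/TFCP2 and NRF1 sites included 1. A consensus match does not show binding, and windows were drawn from the whole organ.

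**Figure D3:**
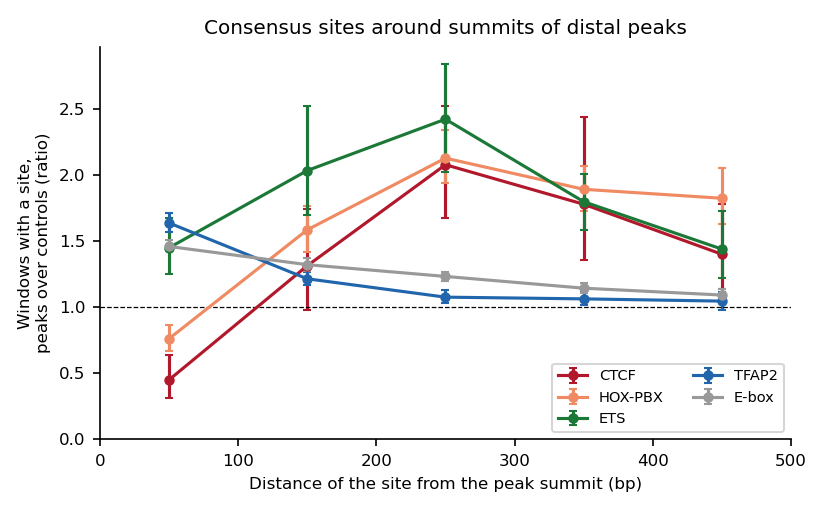
Ratio of windows with a consensus site in distal peaks to control windows (vertical axis) by distance of the site from the summit (horizontal axis, bp, in steps of 100 bp). Points are ratios with 95% bootstrap intervals over chromosomes, with controls matched on GC over the whole 1000 bp window. CTCF and HOX-PBX lie below 1 within 100 bp and above 1 from 200 to 300 bp, while TFAP2 is highest within 100 bp at 1.64. With controls matched on GC over the central 200 bp, ratios were 0.303 for CTCF, 1.01 for HOX-PBX and 1.34 for TFAP2.

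Acetylation was concentrated at promoters. Of replicated peaks, 23.1% had their summit within 1000 bp of a TSS, against 4.53% in shuffles, a ratio of 5.11. Introns held 45.4% (shuffled 41.1%), exons 3.84% (shuffled 3.13%) and intergenic sequence 27.6% (shuffled 51.3%). The 54380 distal peaks had a median fold of 3.64, and the 18403 peaks that overlapped a TSS window had 6.95. The strongest replicated peak, at 65.6-fold on chromosome 5, 115488504 to 115491053, had its summit 140 bp from the small nuclear RNA gene Gm24407. The next were promoter peaks of Hist4h4, a histone H4 gene, at 58.3-fold, Tnrc18 at 55.2-fold, Sp3 at 55.1-fold and Kmt5b, a histone H4 methyltransferase gene, at 53.9-fold.

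Chromosome X carried fewer peaks than any autosome, with 6.33 replicated peaks per Mb against an autosomal median of 31.5 and a lowest value of 22.4 on chromosome 3. Replicate 1 had 8.51 and replicate 2 had 8.55 on X, against autosomal medians of 48.3 and 47.3. Chromosome Y had 3 replicated peaks, at the promoters of Uty and Ddx3y and 9245 bp from Uba1y, genes named after their values were seen. The labels state that embryos of both sexes were pooled, without their proportions.

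**Figure D4:**
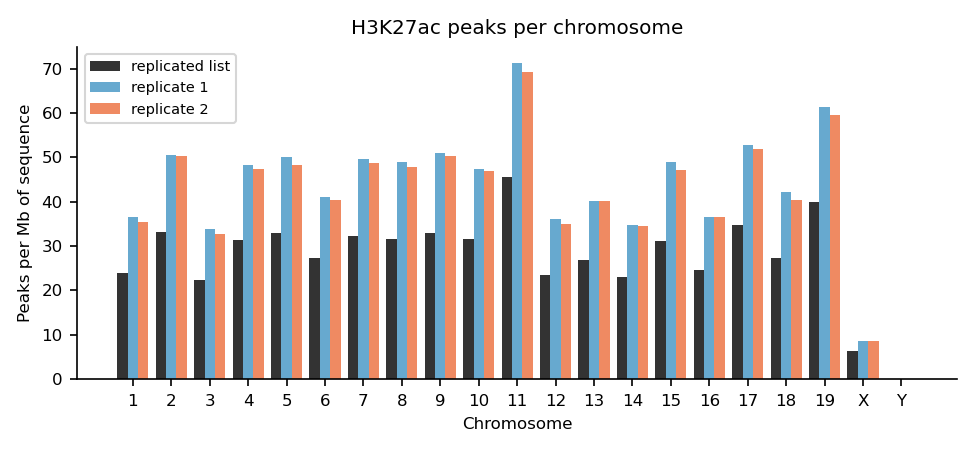
H3K27ac peaks per Mb of sequenced bases (vertical axis) on each mouse chromosome, for the replicated list and each replicate's own list. X has 6.33 replicated peaks per Mb, below the 22.4 of chromosome 3, the lowest autosome.

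The replicates shared their strong peaks and differed at weak ones. Of replicate 1 peaks, 60.4% were shared with replicate 2 (shuffled 3.44%), and of replicate 2 peaks, 62.1% were shared with replicate 1 (shuffled 3.51%). In the lowest quintile by fold 34.4% and 35.1% were shared, and in the highest quintile 99.2% and 99.3%. Across 61004 matched peaks the folds had a Spearman rho of 0.707 and a Pearson r of 0.843 on the log2 scale. Rho was 0.882 at promoters and 0.554 at distal peaks. The median log2 ratio of replicate 2 to replicate 1 was 0.07, with an SD of 0.45 across peaks, and 3.14% of matched peaks differed by more than 2-fold.

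Peaks that touched no peak of the other replicate numbered 37318 in replicate 1 and 34378 in replicate 2, with median folds of 2.95 and 3.06. In replicate 1 the strongest lay in an exon of Ptpn14 (chromosome 1, 189874931 to 189875993) and at the promoter of Mosmo, each at 6.96-fold, followed by introns of Adam19 and Rapgef1 and sequence near Zfp217. In replicate 2 they lay in introns of Slc10a7 at 8.33-fold and Sorbs2 at 7.40-fold, near the kidney-expressed gene Spp2 at 7.15-fold, in an intron of Atp2b2 and near Btn1a1. Of these, 9.67% and 9.99% overlapped a TSS window, against 26.9% and 27.2% of the others. Of the peaks called on both replicates together, 51.6% were in the replicated list. Among replicated peaks, 59993 (82.4%) were touched by peaks of both replicates, 6404 by replicate 1 only, 5589 by replicate 2 only and 797 by neither.

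**Figure D5:**
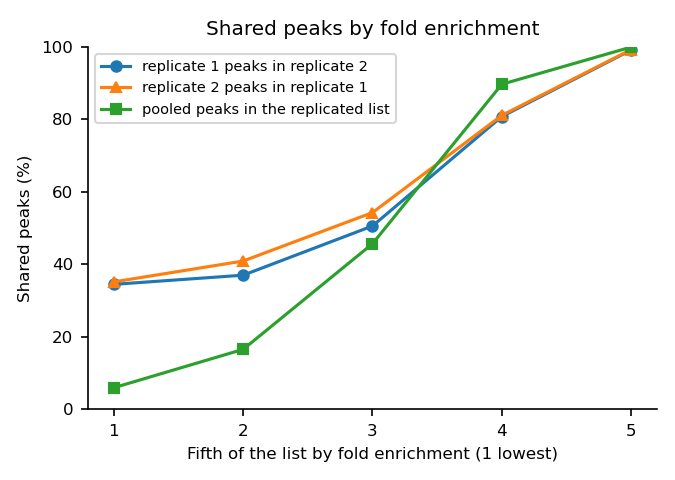
Share of peaks found again (percent, vertical axis) by quintile of fold enrichment within each list (horizontal axis, 1 is the lowest). Lines give replicate 1 peaks in replicate 2, replicate 2 peaks in replicate 1, and peaks called on both replicates together in the replicated list, which rises from 5.90% to 99.98%.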

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

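Peaks on unplaced scaffolds took no part in any comparison, and 9 replicated peaks lay there, above the limit that a count of 0 allows. The strongest, at 38.3-fold, was 1 of 2 on a scaffold assigned to chromosome 4. No explanation was tested.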

How the results depend on the processing

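The tests with a rebuilt replicated share and with only replicated peaks touched by both replicates were chosen only after the result was seen. No paired analysis was possible because the 2 samples form a single group. Depth per sample is unknown, so its effect on list lengths was not tested. The count of marked genes stayed within 1.5 times under all 7 alternatives. Replicate overlap was 66.4% and 68.4% for any shared base, 41.6% and 42.5% for 50% of both peaks, 62.0% and 64.7% for q of 0.01 or less, 61.0% and 61.6% for lists of equal length, 83.0% and 83.8% for the strongest 20000 peaks, and 54.9% of base pairs. Rho was 0.697 for any shared base, 0.775 for 50% of both peaks, 0.724 for q of 0.01 or less, 0.734 over replicated peaks, 0.882 at promoters and 0.554 at distal peaks. The replicated share was 42.3% when rebuilt from both replicates' lists, 42.8% for any shared base, 24.9% for 50% of both peaks and 60.6% for q of 0.01 or less. The promoter share of peaks was 19.7% within 500 bp, 30.2% within 2500 bp, 27.1% by base pairs and 19.6% to 20.3% in single replicates; a wider window takes more summits by construction. Exons held 4.39% and 3.01% with those windows and 4.03% to 4.11% in single replicates. Introns held 47.1%, 41.2%, 44.1% by base pairs and 47.9% to 48.5%, and intergenic sequence held 28.8%, 25.5% and 25.1%. Chromosome X had 0.178 of the autosomal median by base pairs and 0.176 to 0.181 in single replicates, against 0.201. Ranking by length gave 1191 large domains. Windows of 200 bp left 11 sites with intervals above 1, and gave ratios of 0.303 for CTCF, 0.527 for RFX, 0.900 for NRF1 and 1.00 for GRHL/TFCP2. There the intervals of AP-1 (1.01), HNF4 (1.11), HOX-PBX (1.01), Six2-type (1.14) and PAX2/8 sites (1.57) included 1. Matching controls on CpG gave 0.857 for NRF1 and 1.53 for PAX2/8, whose interval then reached 1. NRF1 had 1.40 at q of 0.01 or less and 1.15 to 1.40 in single replicates, and RFX had 1.03 to 1.18. HNF1, NFI, POU5F1-SOX2 and REST sites were too rare for a ratio in windows of 200 bp. With peaks near a TSS left out, adjusted p was 1.00 for nephron progenitor, housekeeping and Hox 9 to 11 genes in domains, all in the opposite direction, 0.946 for Hox 1 to 4, 0.00107 for ureteric bud and 6.29e-04 for stroma. Domains built on promoter peaks are lost there by construction. Ranking by length gave 0.0339 for GDNF and RET, early nephron and podocyte and 3.74e-04 for ureteric bud; stitching over 5000 bp gave 0.00771 for early nephron and stroma and 0.0435 for podocyte. Single replicates gave 0.0339 to 0.432 for GDNF and RET, 0.0854 to 0.0931 for nephron progenitor and 0.0257 to 0.407 for ureteric bud. With promoters matched on CpG, 2 lists were marked more often and 5 less often; adjusted p was 0.137 for nephron progenitor, 0.360 for Hox 9 to 11, 0.904 for GDNF and RET, 0.752 for WNT, 0.134 for housekeeping, 0.453 for macrophage, 0.0775 for adrenal and gonad, 0.0906 for muscle, 0.184 for keratin and 0.0150 for Hox 12 and 13. Early nephron passed with the first TSS (0.0412), where endothelium did not (0.0813), and Hox 1 to 4 passed at 2500 bp (0.0295). At 500 bp, erythroid (0.0122) and liver (0.00722) passed. With only replicated peaks touched by both replicates, erythroid (0.0495), liver (0.00835) and ureteric bud (0.0328) passed. In single replicates, promoter adjusted p was 0.0451 to 0.0571 for Schwann and glia, 0.0167 to 0.0607 for early nephron, 0.00264 to 0.0511 for endothelium, 0.00600 to 0.214 for erythroid, 0.00511 to 0.197 for podocyte and 0.0167 to 0.118 for ureteric bud. For distal peaks, assignment to the nearest TSS gave 2 lists with fewer peaks, with adjusted p of 8.33e-04 for GDNF and RET and for stroma, 0.578 for Hox 1 to 4, 0.545 in the opposite direction for Hox 9 to 11, 0.0550 for endothelium, 0.0641 for pluripotency and 0.161 for transcription factors of other organs. A window of 100 kb gave 0.00786 for GDNF and RET, 0.154 for early nephron and 0.0985 for pluripotency; 20 kb gave 0.0973 for pluripotency and 0.0483 for stroma. At q of 0.01 or less GDNF and RET had 0.05. In single replicates, distal adjusted p was 0.0442 to 0.0462 for GDNF and RET, 0.0350 to 0.0586 for early nephron and 0.0173 to 0.101 for stroma. Beyond the matching and the peaks left out, the cause of these changes was not tested.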

Other observations

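The tests of base composition at summits and of CTCF sites 100 to 300 bp from summits were chosen only after the result was seen.

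Several regulators of kidney development that the rule for named genes left out were marked, and they are named here after their values were seen. Six2, which keeps nephron progenitors undifferentiated, had 8.18-fold (5.10 in replicate 1 and 7.91 in replicate 2) and 5 distal peaks within 50 kb. Foxd1, a marker of stromal progenitors, had 12.3-fold (11.6 and 9.19). Gdnf, the ligand that draws out the ureteric bud, had 12.5-fold (11.3 and 7.32), and its receptor Ret had 3.51-fold (3.23 and 3.48). Lhx1, needed for early nephron structures, had 11.6-fold (10.05 and 11.7).

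Members of the lists that were marked in a single replicate, named after their values were seen, included Lmx1b, Ptpro and Plce1 of the podocyte list in replicate 1 and Epb42, Rhd and Klf1 of the erythroid list in replicate 2. A peak of the other replicate outside the 1000 bp window would not count, and the replicated Klf1 peak lay at the edge of that window. In the liver list, Fga, Fgb and Trf were marked in replicate 1 only and Afp in replicate 2 only. In the stromal list and the 3 Hox lists no member was marked in a single replicate. The same held for the housekeeping, Schwann and glia, muscle, and pluripotency and germ cell lists and for transcription factors of other organs.

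Chromosome X had fewer peaks than its genes or repeats would give. It had 1.09 replicated peaks per protein-coding gene, against at least 2.27 on each autosome, and 11.9 per Mb of unmasked sequence, against at least 34.9. At CpG-rich promoters, marked X-linked genes had a median fold of 9.32 (95% interval 8.40 to 10.1), below the lowest autosome at 11.2. The median over all replicated peaks on X was 4.29, above every autosome (3.82 to 4.03). That median mixes peaks at TSS windows with distal peaks, which had medians of 6.95 and 3.64 over all chromosomes. These classes were not compared separately on X, so it does not show stronger peaks there. Over all protein-coding genes, those on X had a mean of 0.575 distal peaks, against at least 2.30. The promoter value met what a lower active dose of X would give, and that explanation may hold but stays open, since the design held no comparison of sexes and coverage of X was not analysed here.

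CTCF sites were fewer within 100 bp of distal summits than in controls, with a ratio of 0.449 (0.308 to 0.638). They were not alone in this. HOX-PBX sites also lay below 1 in that bin, but had 1.01 in windows of 200 bp. RFX sites had 0.527 (0.352 to 0.750) in windows of 200 bp. GC content as the cause was argued against for CTCF, which had 0.303 (0.188 to 0.481) with controls matched on GC over the central 200 bp. TFAP2 sites, made of G and C, had 1.64 (1.57 to 1.72) within 100 bp. With those closer controls TFAP2 sites had 1.34, so part of that excess went with GC content at the summit. An acetylated nucleosome at the summit beside the site stayed open: CTCF sites 100 to 300 bp away had 1.70, but the ratios above 1 in the whole window and below 1 at its centre already put the flanks above 1. Summits misplaced in wide peaks stayed open: in the narrower peaks the ratio was 0.583 (0.314 to 1.00) from 21 windows and 36 controls. Its interval reached 1, which the rule first written counted for that explanation, but with so few sites it was read here as undecided.

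Matching on promoter CpG narrowed the gap in fold at tubule and endothelial genes. Random lists matched on promoter CpG had medians of 6.10 for proximal tubule, 6.75 for loop of Henle and distal tubule and 7.30 for endothelium, against 10.6 to 10.7 without matching. The list medians still lay at percentiles 1.19, 1.75 and 1.6 of the matched lists, which argued against CpG as the whole cause. Adjusted over 17 lists, these permutation tests gave 0.0748 each and so did not pass the threshold. CpG as the whole cause was therefore left undecided. A small share of tubule and endothelial cells in the organ could also lower fold, and no biological explanation was tested.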
